A study of Sus scrofa with 3 samples.

How the data were processed

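Lung tissue RNA from minipigs was measured on an Affymetrix porcine expression array, a chip on which each transcript is read by sets of short probes near its 3' end. Per the labels' protocols, RNA was extracted with TRIZOL and was amplified and labelled with biotin by a 3' in vitro transcription kit. The 3 arrays are a sham minipig lung, the non-operated lung of a minipig with lung ischemia-reperfusion, and the operated lung of such a minipig. Each of the 3 groups holds 1 array, taken from the sample titles. Whether both lungs with ischemia-reperfusion labels came from 1 animal is not given in the sources used here, nor is whether any array was hybridised with pooled RNA.

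The deposited table holds 1 value per probe set and array on the log2 scale, as its values show. Per the submitters' processing notes the values come from MAS5, an Affymetrix algorithm that scales each array and condenses the probes of a set into 1 signal. The MAS5 version and the scaling target are not given in the sources used here. On the linear scale, the mean signal after trimming 2% from each end was 495.1 for sham, 495.7 for the non-operated lung and 495.9 for the operated lung, so the values arrived with a common scale, and no further scaling was applied for the main results. No detection calls were used. Because MAS5 handles each array separately, a difference in RNA composition between arrays can shift the log2 ratios of all genes together. The median log2 ratio over all counted genes was -0.11 for operated against sham, -0.10 for non-operated against sham and -0.02 for operated against non-operated lung.

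Each array carried 23999 probe sets, of which 64 were reporter controls and 23935 were used. Gene names came from the platform's annotation, which listed a gene for 10267 probe sets. Of these, 10069 had 1 gene and 198 had several, and probe sets with several genes were not named. The remaining 13668 probe sets are unnamed here. By gene identifier, 9961 of the singly named probe sets matched the RefSeq gene table of the pig assembly Sscrofa11.1, and 0 symbols needed an update. The named probe sets covered 6765 gene symbols, of which 9 were shared by more than 1 gene identifier. Where a gene had several probe sets, the one with the highest mean log2 signal over the 3 arrays stood for it. The table had 0 further columns of values.

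The floor for low values was each array's median signal over non-control probe sets, 160.7 for sham, 158.6 for the non-operated lung and 158.7 for the operated lung on the linear scale. A gene was counted in a comparison when it lay above the floor on at least 1 of its 2 arrays, and a value at or below the floor was set to the floor. A ratio with 1 value at the floor is therefore a lower bound and is given as at least that fold. Ratios are differences of log2 signal, and a gene is counted as higher or lower when they differ by at least 2-fold, which is 1 on the log2 scale. With 1 array per group there is no spread between animals to test against, so no p-values are given and the number of arrays limits the precision. The spread between probe sets of the same gene within a comparison is the only internal measure of error here. It covers differences between probe sets read on the same arrays, and not between repeat arrays, RNA preparations or animals.

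Before the data were examined, the comparisons, the floor, the thresholds, most of the alternatives, 47 gene lists and the rule for naming genes were set. For each list, the median log2 ratio of the members above the floor was placed among the medians of 10000 random lists of the same size, matched on mean signal in 10 bins. A list is said to stand apart when its median lay in the lowest or highest 2.5% of random lists. This describes these arrays and is not a test of the conditions. Lists with fewer than 5 genes above the floor received counts but no percentile. After the comparisons had been seen, 7 more lists were written, before the values of their genes were looked at.

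Genes are named by a rule with 4 parts. In each comparison the first part takes the 10 highest and 10 lowest log2 ratios among genes above the floor on both arrays, with the higher value at least 4 times the floor and all above-floor probe sets of the gene on the same side. The next part takes the 5 largest lower bounds in each direction among genes at or below the floor on 1 array. From each list up to 4 members with the largest ratios of at least 2-fold are taken, with the same condition on probe sets. For both lungs together, the 5 highest and 5 lowest genes by the smaller of their ratios against sham are taken. Symbols that are only locus numbers were passed over. Genes named outside this rule are marked as chosen after their values were seen.

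The share of genes that chance alone would place beyond 2-fold against the same sham array in both lungs was estimated from 100 simulated pairs of unchanged arrays, with noise taken from the spread of log2 ratios between the operated and the non-operated array in 20 signal bins, which holds no spread between sham and other animals. The steps were tested on simulated operated and sham arrays over 6765 genes. Base signals came from the mean of the operated and the non-operated array, and noise from the spread of their ratios. No sham values entered, so the error rates below hold no spread between sham and other animals. The changed genes were drawn only from genes well above the floor, so recovery of dim genes was not tested. Of 100 such genes simulated with a 4-fold difference 100 were called, and of 100 with a 1.5-fold difference 5 were called. Of 4767 unchanged genes counted 8 were called, which is 0.168%. Of 100 unchanged lists of 15 genes, 5 stood apart, and a changed list reached percentile 100.

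The alternatives were quantile normalization, centring of each array on its median over probe sets above the floor on all arrays, a loess curve of the ratio on mean signal with a span of 0.4 and 3 iterations, no floor, a floor at the 25th or the 75th percentile, a pseudocount at the array median in place of the floor, the mean of all probe sets of a gene, and each list without its farthest member. A floor at the 95th percentile of the reporter probe sets was added after the data had been seen. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Image files of the arrays and probe-level intensities were not used here, and no genome coordinates are given.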

Results

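The data are signals of 23935 probe sets on 3 Affymetrix porcine arrays, covering 6765 named genes. They come from the lungs of minipigs, a small breed of pig used as a surgical model. In the ischemia-reperfusion animals the left pulmonary artery was closed for a time and reopened without involving the bronchus, so that the lung stayed ventilated while its arterial blood flow was interrupted. The operated lung is the left lung on the occluded side, the non-operated lung is the right lung of a minipig with the same procedure, and the sham lung comes from a sham minipig. Each group is 1 array, so no difference below has a replicate check or a p-value. On the log2 scale the median signal was 7.33 for sham, 7.31 for the non-operated lung and 7.31 for the operated lung, and the highest signal was 14.83, 14.92 and 14.79. The first pair of comparisons sets each lung after ischemia-reperfusion against sham, and the last sets the occluded side against the other side.

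In the operated lung, lists of vessel wall, alveolar type 1 and glucocorticoid-responsive genes had higher signals than in sham, and lists of cell division genes and of B and T cell markers had lower signals. HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1, was 12.5-fold higher. FCN2, a ficolin of the lectin complement pathway, was at least 55.9-fold higher, and PDK4, a kinase that restrains pyruvate oxidation, was at least 36.3-fold higher. CXCL13, the chemokine that draws B cells into follicles, was 30.0-fold lower, and the B-cell receptor component CD79B was at least 14.98-fold lower. Of 5097 genes counted, 441 were at least 2-fold higher and 448 at least 2-fold lower, together 17.4%. At a 4-fold threshold, 83 genes were higher and 74 lower.

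Among the other genes with the highest ratios, DUOX2, a hydrogen peroxide producing oxidase of airway epithelium, was 12.4-fold higher from a sham signal at the edge of the floor. The flavin monooxygenase FMO1 was 9.89-fold higher, and S100A9, a calcium-binding protein of neutrophils and monocytes, was 8.92-fold higher. AGTR1, the type 1 angiotensin II receptor, was 8.84-fold higher. SHROOM2, VSIG2, AKR1CL1, PLA2G1B and ENPP1 lay between 8.78-fold and 6.77-fold higher. CYP7A1, the first enzyme of bile acid synthesis in the liver, was at least 17.0-fold higher, the platelet chemokine gene PPBP at least 14.5-fold and the glucuronosyltransferase UGT2B31 at least 12.8-fold. On the lower side, the chemokine CXCL14 was 16.8-fold lower, LTB, which encodes lymphotoxin beta of lymphoid tissue, 13.1-fold and SERPINI1 12.3-fold. C3H2orf40 was at least 31.5-fold lower, the B-cell transcription factor SPIB at least 8.98-fold and the proton pump subunit ATP6V1C2 at least 8.05-fold.

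Cell division genes formed the list with the lowest median in this comparison under each scaling, floor and probe set choice tried. Of 24 cell cycle genes above the floor, 23 were at least 2-fold lower in the operated lung and 0 were higher, with a median log2 ratio of -2.22. TOP2A, the topoisomerase that untangles replicated DNA, was 12.7-fold lower, the mitotic cyclin CCNB1 11.1-fold and RRM2, a subunit of ribonucleotide reductase, 9.72-fold. PCLAF and DLGAP5 were each 9.23-fold lower, BIRC5, the survivin gene, was 8.36-fold lower and the cyclin CCNB2 at least 7.51-fold lower. B and plasma cell markers were on the same side, with a median of -1.66 and 4 of 7 genes at least 2-fold lower, among them BLNK at -1.73 and TNFRSF17 at -1.66. T and NK cell markers had a median of -0.80, with 5 of 11 genes lower and 1 higher. The T-cell kinase LCK was at -1.93 and the T-cell receptor chain CD3G at -1.69. A further list of lymphoid genes, written after these comparisons had been seen, had a median of -1.11 with 8 of 12 genes lower. The 3 earlier lists stood in the lowest 2.5% of random lists under the main setting and under every alternative scaling and floor that left them enough genes.

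Markers of the vessel wall and of the thin alveolar epithelium had higher signals. Of 15 endothelial markers, 12 were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.23. The ratio was 1.98 for THBD, which encodes the anticoagulant receptor thrombomodulin, 1.96 for the sphingosine 1-phosphate receptor S1PR1, 1.798 for the endothelial cadherin CDH5 and 1.74 for the angiopoietin receptor TEK. Of 8 alveolar type 1 cell markers, 5 were higher and 0 lower, with a median of 1.15, including HOPX at 2.40 and the caveolin genes CAV2 at 2.03 and CAV1 at 1.23. Smooth muscle and pericyte markers had a median of 1.24, with 6 of 10 higher. ACTG2, a smooth muscle actin, was at 2.54 and TAGLN at 1.67, while the pericyte gene RGS5 was at least 7.11-fold lower. The list of alveolar type 2 cell and surfactant genes had a median of 0.67, with 3 of 9 higher. SFTPB, which encodes surfactant protein B, was at 1.23 and the phosphate transporter SLC34A2 at 1.29. Chosen after their values were seen, the surfactant genes SFTPC and SFTPA1 were at 0.08 and 0.10, with SFTPC near the highest signal on each array. The type 2 list stood apart in this comparison but not when all probe sets of a gene were averaged, which gave a median of 0.19.

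Monocyte and macrophage markers had a median of 1.04, with 8 of 15 genes at least 2-fold higher and 1 lower. The complement receptor gene VSIG4 was at 2.56, the mannose receptor MRC1 at 2.53 and the hemoglobin scavenger receptor CD163 at 2.01, while CHI3L1, a chitinase-like protein, was at -1.89. Of 8 neutrophil and granule genes, 3 were higher and 1 lower, and the list lay within the range of random lists at a median of 0.39. For the neutrophil and granule genes the median was 0.67 and stood apart without a floor, 0.15 at a floor on the 25th percentile and -0.097 at a floor on the 75th percentile. Its higher members were S100A9, S100A12 at 1.72 and S100A8 at 1.44. Endothelial activation and leukocyte adhesion genes had a median of 0.74 with 2 of 9 higher and 2 lower. ICAM2 was at 1.58 and ICAM1 at 1.42, whereas VCAM1 was at -1.63 and the mucosal addressin MADCAM1 was at least 2.14-fold lower. Chemokines and pro-inflammatory cytokines had a median of -0.30 within the random range, with 2 of 15 higher and 4 lower. CCL4 was at 2.02, the monocyte chemokine CCL2 at -1.98, IL18 at -1.93 and the lymphoid chemokine CCL19 at -1.79.

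Genes that respond to glucocorticoids had a median of 1.48, with 9 of 14 at least 2-fold higher and 0 lower. Besides PDK4, the transcription factors KLF9 and CEBPD were at 2.47 and 2.26 and the glucocorticoid receptor co-chaperone FKBP5 was at 2.18. Immediate early genes, which are transcribed within minutes of a stimulus, had a median of 1.07 with 13 of 21 higher and 0 lower. PTGS2, the inducible cyclooxygenase, had a ratio of at least 2.59, and CYR61 and EGR1 were at 2.28 and 2.01. Of 5 circadian clock genes, 3 were higher with a median of 1.08, led by PER1 at 1.81 and NFIL3 at 1.34. PER1 is also a member of the glucocorticoid list and NFIL3 of the immediate early list. Interferon response genes had a median of 0.41 with 8 of 24 higher and 1 lower. RSAD2 was at 2.33, OAS1 at 2.30 and IFIT3 at 1.99, and PLAC8 was at -2.57.

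Stress lists had smaller medians. Oxidative stress and NRF2 target genes had a median of 0.26 with 7 of 22 higher and 0 lower, among them the quinone reductase NQO1 at 2.38, the metallothionein MT-2B at 1.93 and GCLC, which makes the precursor of glutathione, at 1.83. Hypoxia and HIF target genes had a median of 0.45 with 4 of 19 higher and 0 lower, including the oxygen-regulated factor EPAS1 at 1.71, INSIG2 at 1.69 and MXI1 at 1.27. At a floor on the 75th percentile the hypoxia list no longer stood apart, with a median of 0.08. Heat shock and chaperone genes had a median of 0.28 with 5 of 19 higher, among them CRYAB at 1.96 and DNAJB4 at 1.84, and lay within the random range with a pseudocount and at floors on the 25th or 75th percentile or the reporter probe sets. Unfolded protein response genes had a median of -0.29 within the random range, with ATF3 at 1.78 and the protein disulfide isomerase PDIA6 at -1.34. Apoptosis genes had a median of -0.25 with 1 of 16 higher, TNFRSF1A at 1.05, and 1 lower, the survivin gene BIRC5. Inflammasome genes had a median of 0.01 over 5 genes, with GSDMD at 1.24, TXNIP at 1.05 and IL18 lower.

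Energy and protein synthesis lists lay to the lower side. Of 39 oxidative phosphorylation genes, 3 were at least 2-fold lower and 35 had ratios below 0, with a median of -0.48. ATP5I and ATP5L, subunits of ATP synthase, were at -1.99 and -1.19 and NDUFB3 of complex I was at -1.15. The list of cytosolic ribosomal proteins had a median of -0.35, with 55 of 56 below 0 and 0 beyond 2-fold, and they stood apart except under quantile normalization, where the median was -0.15. Reference genes often used for normalization had a median of -0.44 within the random range and below 0 under every scaling, with HPRT1 at -1.24 and GUSB at -1.17. Glycolysis enzymes had a median of -0.29 within the random range, with 1 of 15 higher, the hexokinase HK3 at 1.48. They stood apart to the lower side without a floor, at a floor on the 25th percentile or the reporter probe sets, with a pseudocount and with the mean of all probe sets, where the median reached -0.70.

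Of the matrix lists, fibroblast and extracellular matrix genes had a median of 0.40 with 4 of 22 higher and 3 lower. The metalloproteinase inhibitor TIMP3 was at 2.42, the basement membrane collagen COL4A2 at 1.52, the collagen cross-linking enzyme LOX at 1.46 and lumican, LUM, at -1.24. Metalloproteinases and their inhibitors had a median of 0.59 with ADAMTS1 at 2.12 and TIMP1 at -1.15, and that list stood apart only in the main setting and with a pseudocount, not under the 3 other scalings, the other floors that left it enough genes, or the mean of all probe sets. Angiogenic factors had a median of 0.48 with 2 of 10 higher, CYR61, also of the immediate early list, and TEK, also of the endothelial list. Renin-angiotensin, endothelin and natriuretic peptide genes had a median of 0.76 with 1 of 6 higher, AGTR1. Alveolar fluid transport genes had a median of 0.58 with 2 of 7 higher, the water channels AQP1 at 1.14 and AQP5 at 1.06. AQP1 is also a member of the endothelial list and AQP5 of the alveolar type 1 list. Junction genes had a median of 0.59 with 3 of 10 higher, OCLN at 1.48 and CDH5 and CLDN5 at 1.798 and 1.09, which are also members of the endothelial list. Acute phase genes had a median of 0.56 with 3 of 8 higher and 1 lower, with ITIH3 at no less than 2.17, HP, the hemoglobin-binding haptoglobin, at 1.28 and the serum amyloid gene SAA2 at -1.77. It no longer stood apart at a floor on the 75th percentile, and the same floor ended the call in the non-operated lung. Striated muscle genes had a median of 0.54 over 5 genes, with ANKRD1 at no less than 2.10 and PLN at no less than 1.54. In either lung they lay within the random range at a floor on the 25th percentile or the reporter probe sets. Over the alternatives their median ran from 0.005 to 2.36 in the operated and from 0.098 to 2.42 in the non-operated lung.

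Complement genes had a median of 0.00 and members on both sides, with 3 of 19 higher and 4 lower. The properdin gene CFP was at 1.57, C4A was at -2.24, CLU at -1.91 and C7 at -1.81. Coagulation genes had a median of 0.33 within the random range, with THBD, VWF at 1.21 and the tissue factor gene F3 at 1.01 higher and 0 of 12 lower. Prostaglandin and leukotriene pathway genes had a median of -0.21, which was 0.38 at a floor on the 75th percentile, and a mean of 0.49, with PTGS2, PTGS1 at 1.62 and ALOX5AP at 1.47 higher. MHC class I genes had a median of 0.03, with SLA-3 at 2.67 and PSMB8 at -1.29, and MHC class II genes a median of -0.22 with 1 of 10 lower, the class II transactivator CIITA at -1.07. NADPH oxidase and nitric oxide synthase genes had a median of -0.10 and a mean of 0.09, with DUOX2 higher and RAC2 at -1.36. In 8 lists fewer than 5 genes lay above the floor. Their members beyond 2-fold were TLR4 at 1.65 and TLR2 at 1.10 of the Toll-like receptor list, GATA2 at 1.20 and MS4A2 at 1.06 of the mast cell list, ALAS2 with at least 1.11 of the red blood cell list, PPBP and CD9 at 1.60 of the platelet list, TFF3 at 1.07 of the airway gland list, and LPL at 2.45 and PPARG with at least 1.63 of the adipocyte list. The ciliated and mesothelial lists had 0 such members.

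**Figure D1:**
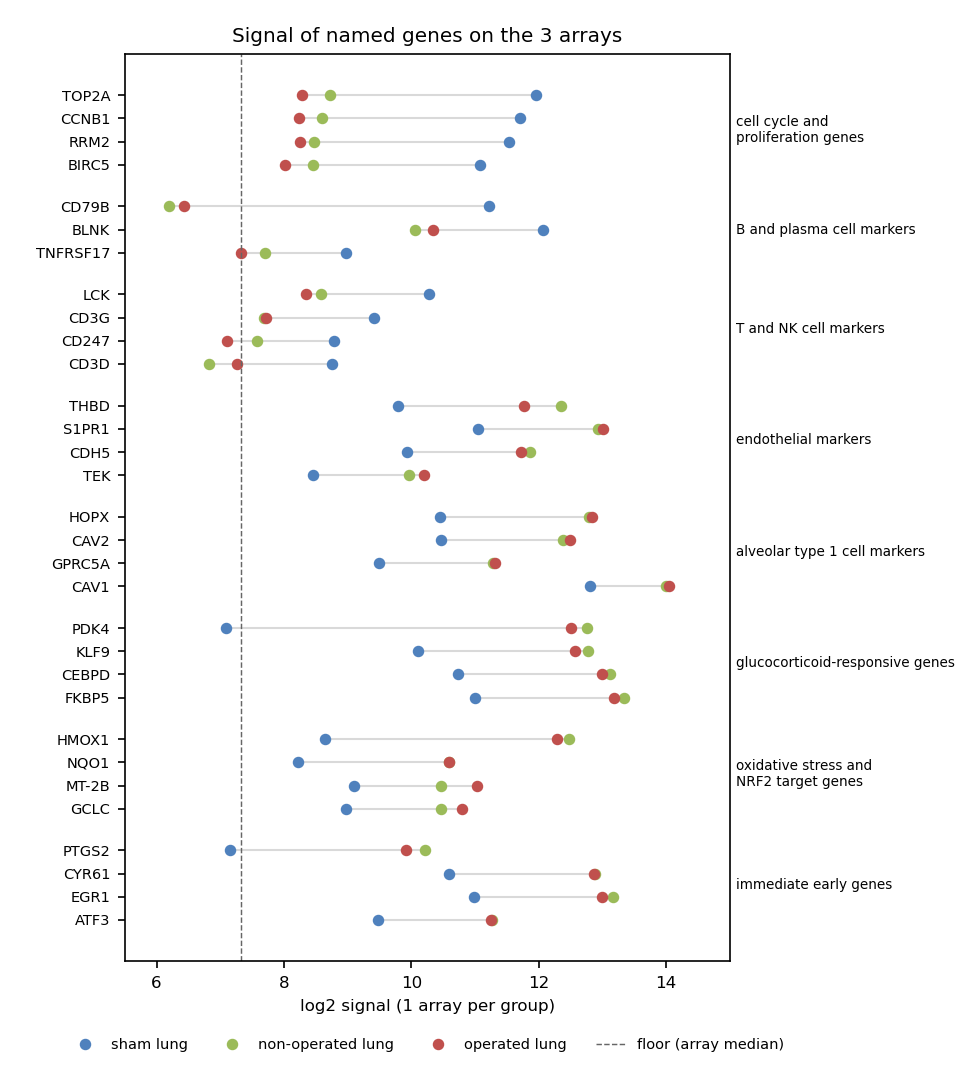
Log2 signal on the sham, non-operated and operated array for genes named from 8 of the lists, with the floor as a dashed line. TOP2A and CCNB1 lie lower on both ischemia-reperfusion arrays than on sham, by ratios of -3.67 and -3.47 in the operated lung, and THBD and KLF9 lie higher, by 1.98 and 2.47.

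Of 39 lists with enough genes, 21 stood apart to the higher side and 5 to the lower side in the operated lung against sham. Random lists of unrelated genes would give 1.95. Genes within a list are related and some belong to several lists, so this number is not an error rate. Of these 26 lists, 19 stood apart under each alternative scaling, floor or probe set choice. Of 186 genes beyond 2-fold with several probe sets above the floor, 179, or 96.2%, had all of them on the same side.

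The non-operated lung differed from sham by about as many genes as the operated lung. HMOX1 was 14.2-fold higher, FMO1 11.5-fold, S100A9 10.9-fold and DUOX2 9.48-fold. FCN2 was at least 51.1-fold higher and PDK4 at least 43.0-fold. CXCL13 was 19.4-fold lower, CXCL14 17.6-fold and LTB 12.7-fold, and C3H2orf40 was at least 31.5-fold lower. Of 5113 genes counted, 458 were at least 2-fold higher and 437 lower, together 17.5%, and at a 4-fold threshold 82 were higher and 71 lower.

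Further genes with high ratios were TMEM100, an endothelial gene of the bone morphogenetic protein pathway, at 8.59-fold, VSIG2 at 8.50-fold, AGTR1 at 8.10-fold, AKR1CL1 at 7.84-fold, PHLDA2 at 7.75-fold and TACC1 at 7.52-fold. PPBP was at least 16.9-fold higher and CYP7A1 at least 12.3-fold. EIF1AY, a translation factor gene of the Y chromosome, was at least 10.2-fold higher than in sham. On the lower side the peptide transporter SLC15A2 and EAF2 were 8.36-fold and 8.34-fold lower, SERPINI1 was 9.17-fold lower, CD79B at least 14.99-fold, SPIB at least 8.98-fold, ATP6V1C2 at least 8.06-fold and the replication factor RFC3 at least 7.35-fold lower.

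Cell cycle genes had a median of -2.04, with 23 of 24 at least 2-fold lower. TOP2A was 9.40-fold lower, PCLAF 9.26-fold, CCNB1 8.57-fold and RRM2 8.39-fold, and UBE2C, which marks mitotic proteins for degradation, was at -2.80. B and plasma cell markers had a median of -1.32 with 5 of 7 lower, among them BLNK at -2.004 and CD40 at -1.32. T and NK cell markers had a median of -0.73 with 5 of 11 lower, including CD3G at -1.72 and LCK at -1.70, and 1 higher, the cytotoxic granule gene GNLY with a ratio of at least 1.60. The later list of lymphoid genes had a median of -1.09 with 9 of 12 lower.

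Endothelial markers had a median of 1.51, with 11 of 15 at least 2-fold higher and 0 lower. THBD was at 2.57, RAMP2 at 2.003, CDH5 at 1.94 and S1PR1 at 1.90. Glucocorticoid-responsive genes had a median of 1.503 with 11 of 14 higher, including KLF9 at 2.68, CEBPD at 2.40 and FKBP5 at 2.35. Immediate early genes had a median of 1.29 with 14 of 21 higher, led by PTGS2 with at least 2.89, CYR61 at 2.29, EGR1 at 2.17 and NR4A3 at 2.10. Alveolar type 1 markers had a median of 1.28 with 6 of 8 higher, among them HOPX at 2.34, CAV2 at 1.91 and AQP5 at 1.37. Smooth muscle markers had a median of 1.19 with 5 of 10 higher, including ACTG2 at 2.31 and TPM2 at 1.83, and RGS5 again at least 7.11-fold lower. Circadian genes had a median of 1.19 with PER1 at 2.13 and NFIL3 at 1.68. Macrophage markers had a median of 1.12 with 8 of 15 higher, among them MRC1 at 2.44, VSIG4 at 2.38, CD163 at 1.996 and LGALS3 at 1.34.

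Alveolar type 2 genes had a median of 0.12 within the random range, with 1 of 9 higher, the transcription factor ETV5 at 1.30. Interferon response genes had a median of 0.58 with 7 of 24 higher, including OAS1 at 2.16, IFIT2 at 1.92 and IFIT3 at 1.85, and PLAC8 at -2.60. Hypoxia and HIF target genes had a median of 0.49 with 5 of 19 higher, among them EPAS1 at 1.61 and ADM, the vasodilator peptide adrenomedullin, at 1.43, and the list again lay within the random range at the higher floor, with a median of 0.06. NRF2 targets had a median of 0.35 with NQO1 at 2.38, GCLC at 1.497 and MT-2B at 1.36 among 7 of 22 higher genes. Heat shock genes had a median of 0.33 with 7 of 19 higher, including CRYAB at 2.34, HSPA6 at 1.37 and HSP70.2 at 1.37, and lay within the random range at the same 3 floors. Prostaglandin and leukotriene pathway genes had a median of 0.63 with PTGS1 at 1.83 and ALOX5AP at 1.55, but the list lay within the random range at 2 lower floors and with a pseudocount, and the median was -0.09 without the member farthest from it. Renin-angiotensin genes had a median of 0.97 with 3 of 6 higher, AGTR1, ADM and AGT at 1.25.

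Metalloproteinases and inhibitors had a median of 0.79 with 3 of 6 higher, TIMP3 at 2.62, ADAMTS1 at 2.65 and TIMP2 at 1.08, and lay within the random range when all probe sets of a gene were averaged. Matrix genes had a median of 0.30 with 4 of 22 higher, including COL4A2 at 1.60, and 1 lower, FAP at -1.09. Adhesion genes had a median of 0.55 with ICAM1 at 1.48, ICAM2 at 1.47 and VCAM1 at -1.67. Fluid transport genes had a median of 0.51 with AQP1 at 1.55, junction genes 0.49 with OCLN at 1.49 and CLDN7 at 1.11, acute phase genes 0.61 with HP at 1.46 and SAA2 at -1.74, and striated muscle genes 0.64 with PLN at no less than 1.61. Neutrophil and granule genes had a median of 0.26 within the random range with S100A8 at 2.21 and S100A12 at 1.71. They stood apart to the higher side without a floor and at floors on the 25th percentile or the reporter probe sets, with medians of 0.55, 0.48 and 0.58. Chemokines and cytokines had a median of -0.33, also within that range, with CCL4 at 1.999, IL18 at -2.08, CCL19 at -2.04 and CCL2 at -1.72. Angiogenic factors had a median of 0.18, coagulation genes 0.27 with VWF at 1.58, complement genes 0.19 with CFP at 1.57 and CLU at -1.51, and these 3 lists lay within the random range. Complement genes stood apart to the higher side without a floor, at 0.30, and angiogenic growth factors and receptors did so without a floor, at floors on the 75th percentile or the reporter probe sets and with a pseudocount, with medians up to 0.60.

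On the lower side, oxidative phosphorylation genes had a median of -0.44 with 38 of 39 below 0 and ATP5I at -1.19. Cytosolic ribosomal proteins had a median of -0.25 with 53 of 56 below 0, and the commonly used reference genes had a median of -0.47 with HPRT1 at -1.36 and GUSB at -1.07. Under quantile normalization and loess the ribosomal medians of -0.14 and -0.17 and the reference gene medians of -0.38 and -0.40 lay within the random range, as both lists did with the mean of all probe sets. Glycolysis enzymes at -0.26 lay within it too, but stood apart to the lower side with a pseudocount and at floors on the 25th or 75th percentile or the reporter probe sets, with medians down to -0.47. Unfolded protein response genes at -0.24 with DNAJB11 at -1.10, apoptosis genes at -0.26 with CASP8 at -1.02, MHC class II genes at -0.26, MHC class I genes at -0.03 with SLA-3 at 2.77, NADPH oxidase genes at 0.06 with RAC2 at -1.72 and inflammasome genes at -0.00 with TXNIP at 1.21 lay within the random range. In the lists with fewer than 5 genes above the floor, TLR2 was at 1.39, GATA2 at 1.77, CD9 at 1.70, LPL at 2.11 and MS4A2 at 1.799, which was -0.017 at a floor on the 75th percentile. In this comparison 20 lists stood apart to the higher side and 6 to the lower side, and 18 of these 26 did so under each alternative scaling, floor or probe set choice.

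**Figure D2:**
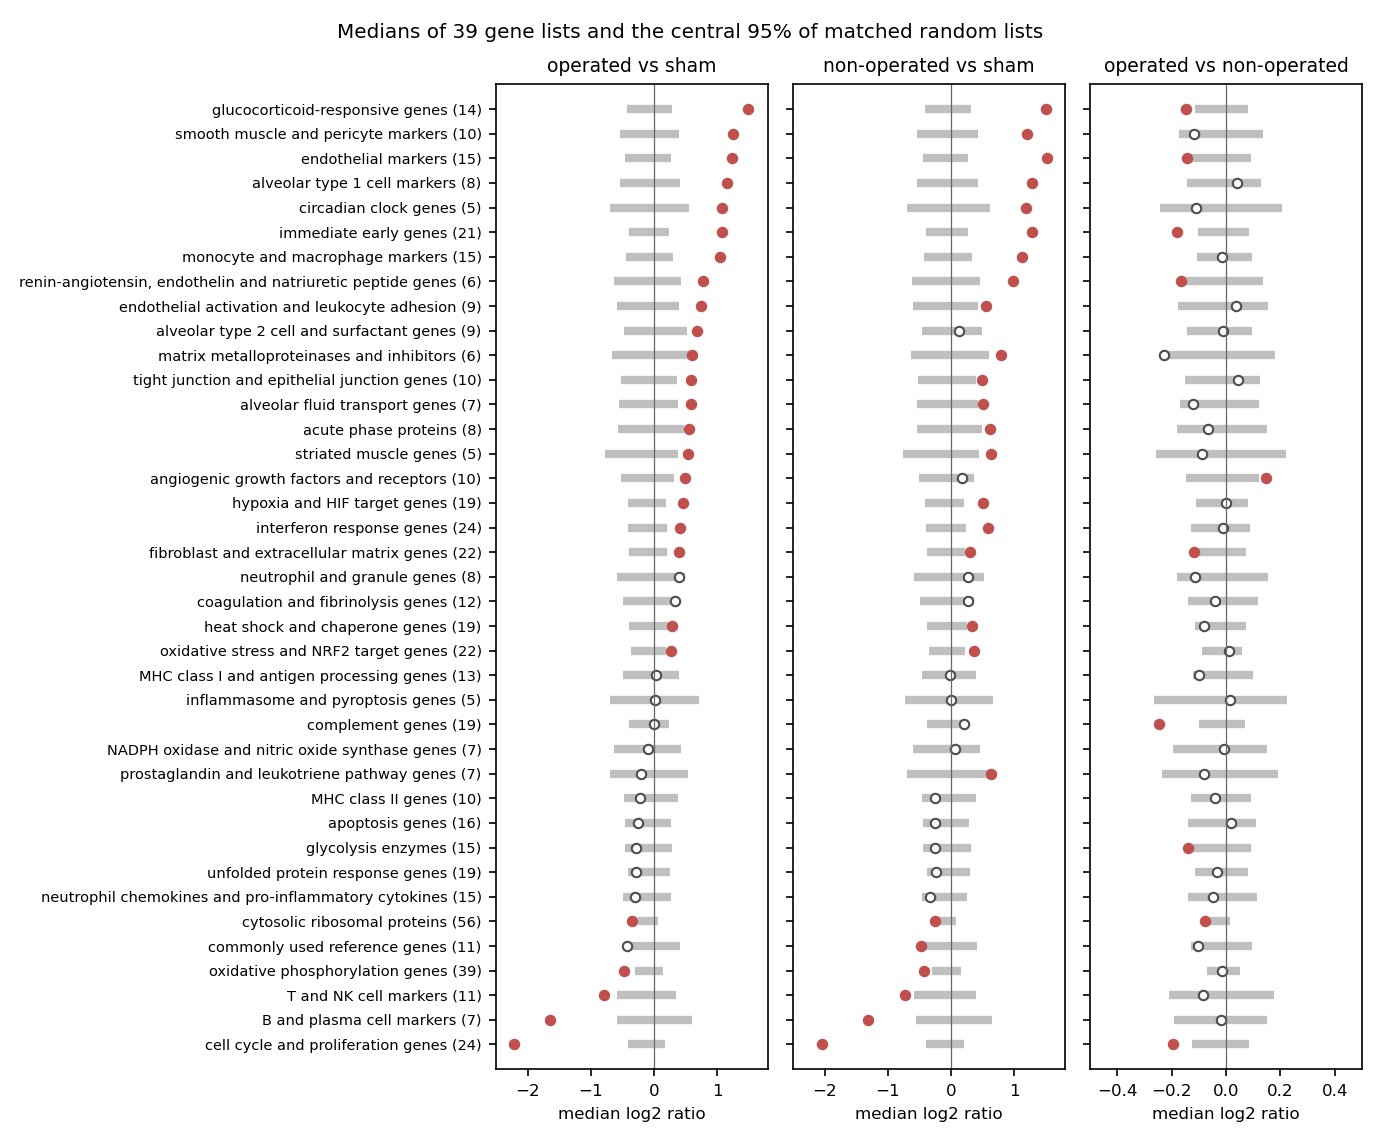
Median log2 ratio of each of 39 gene lists in the 3 comparisons, with grey bars for the central 95% of 10000 matched random lists, filled points for lists that stand apart and open points for the others, and the number of genes above the floor in parentheses. Cell cycle genes lie lowest in both comparisons with sham, at -2.22 and -2.04, and the panel of operated against non-operated lung has a narrower axis, with complement genes lowest at -0.25.

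Set side by side, both lungs differed from the sham array in the same direction at most genes beyond 2-fold. Of 5050 genes counted in both comparisons, 371 were at least 2-fold higher in both lungs, 364 were lower in both and 0 were higher in one and lower in the other. Ranked by the smaller ratio, FCN2 was at least 51.1-fold higher, PDK4 at least 36.3-fold, PPBP at least 14.5-fold, HMOX1 12.5-fold and CYP7A1 at least 12.3-fold. On the other side, C3H2orf40 was at least 31.5-fold lower, CXCL13 19.4-fold, CXCL14 16.8-fold, CD79B at least 14.98-fold and LTB 12.7-fold. Independent lists of these sizes would share 39.996 higher and 38.8 lower genes, and unchanged arrays simulated against 1 sham array shared 0.03 higher and 0.46 lower genes. Across genes, which are not independent replicates, the log2 ratios of the lungs had a correlation of 0.953 against a simulated 0.506 and a covariance of 0.647 against a simulated 0.0340. With 1 sham array the controls cannot be split, so part or all of the excess may come from the shared sham array. The simulation gave sham the same base signals as the lungs, so it cannot say how much.

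**Figure D3:**
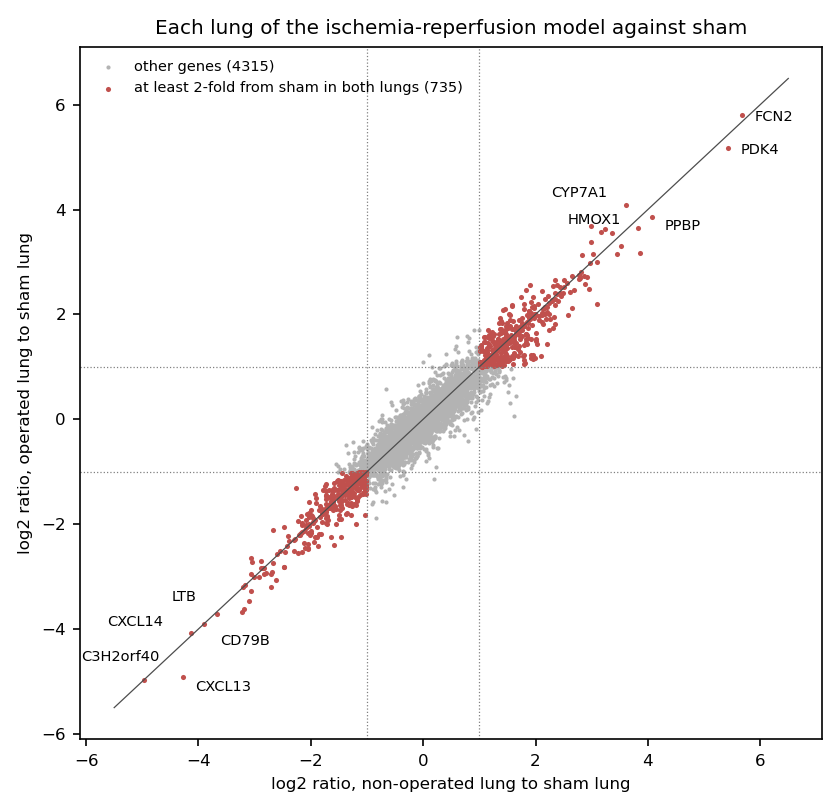
Log2 ratio to sham of the non-operated lung on the x axis and of the operated lung on the y axis for 5050 genes, with the line of equal ratios. The 371 genes at least 2-fold higher and the 364 at least 2-fold lower in both lungs are red, the other genes are grey, and FCN2, PDK4, CXCL13 and C3H2orf40 are among the labelled genes farthest from 0.

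Between the operated and the non-operated lung, few genes differed by 2-fold. SFTPB, the gene of surfactant protein B, was 2.18-fold higher in the operated lung, and TIMP1, an inhibitor of metalloproteinases, was 2.54-fold lower. Of 4944 genes counted, 3 were at least 2-fold higher in the operated lung and 9 lower, together 0.243%, and 0 reached 4-fold. These counts depended on the floor, with 47 higher and 63 lower at the 25th percentile, 29 and 68 at the reporter floor, 231 and 319 without a floor and 1 and 4 at the 75th percentile. In the main setting the higher genes besides SFTPB were NCOA7, at least 2.34-fold, and COL5A3 at a log2 ratio of 1.09. The lower genes were TIMP1, FGF13 and SCARA5, each of the last pair 2.32-fold lower, CHI3L1 at 2.07-fold, FKBP10 at no less than 2.19-fold lower, ADGRG1 at -1.55, CYP1A1 at -1.23, LIMS1 at -1.13 and MVB12B at -1.04. COL5A3, ADGRG1, CYP1A1, LIMS1 and MVB12B lie outside the naming rule, since their higher signal was under 4 times the floor, and were chosen after their values were seen. Of the genes beyond 2-fold between the lungs, 0 had several probe sets above the floor, so no further probe set could check them. At a 1.5-fold threshold, 65 genes were higher and 104 lower. The SD of log2 ratios was 0.26, against 0.82 for operated lung and sham, and the correlation of signals across genes was 0.986, against 0.872.

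Other genes with high ratios were RSL24D1 and RPF1, which act in ribosome assembly, at 1.88-fold and 1.84-fold, the kinase FYN at 1.75-fold, DHX29 and CXXC5 at 1.69-fold, INSIG2 at 1.63-fold and UGT2B31 at 1.61-fold, followed by REXO2 at 0.67 and ZFAND2A at 0.66 on the log2 scale. FAM234A, PRSS8, HNMT and SLC25A11 were at least 1.76-fold, 1.61-fold, 1.58-fold and 1.57-fold higher from values at the floor in the non-operated lung. Lower in the operated lung were MCF2L at 1.99-fold, TMEM100 at 1.88-fold, the orphan nuclear receptor NR4A3 at 1.87-fold, the chemokine CCL24 at 1.85-fold, the mitochondrial membrane protein TSPO at 1.84-fold and YIF1A at 1.83-fold. TBXAS1, the thromboxane synthase gene, was at least 1.79-fold lower, and NQO2, MXD3 and POLD2 were at least 1.65-fold, 1.63-fold and 1.63-fold lower.

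In the operated against the non-operated lung, complement genes had a median of -0.25, with 15 of 19 ratios below 0, 4 above 0 and 0 beyond 2-fold. Chosen after their values were seen, C9 was at -0.81, C4A at -0.78, CFB at -0.48, C7 at -0.44 and CLU at -0.40. Immediate early genes had a median of -0.18 with 19 of 21 ratios below 0 and 0 beyond 2-fold, among them NR4A3 at -0.90. These 2 lists of the 10 that stood apart did so under each alternative scaling, floor or probe set choice. Cell cycle genes had a median of -0.19, with 16 of 24 ratios below 0, 2 above 0, the rest at the floor in both lungs and 0 beyond 2-fold. They lay within the random range at a floor on the 75th percentile. Renin-angiotensin genes had a median of -0.17, glucocorticoid-responsive genes -0.15, endothelial markers -0.14, glycolysis enzymes -0.14 and fibroblast and matrix genes -0.12, and angiogenic factors were the list that stood apart to the higher side, at 0.15. Each of these 6 lists lost its place outside the random range under at least 1 alternative. A pair of them changed direction, the renin-angiotensin, endothelin and natriuretic peptide genes to 0.12 without the member farthest from the median and the angiogenic growth factors and receptors to -0.0078 with the mean of all probe sets. Ribosomal protein genes had 47 of 56 ratios below 0 and 0 beyond 2-fold, with a median of -0.08, which became 0.00 under quantile normalization.

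The other lists lay within the random range. Among them T and NK markers had a median of -0.08, B and plasma cell markers -0.02, macrophage markers -0.02, hypoxia targets 0.00, NRF2 targets 0.01, interferon response genes -0.01 and oxidative phosphorylation genes -0.02. The alveolar type 2 list had a median of -0.01 with SFTPB as its 1 member beyond 2-fold, the type 1 list 0.04, smooth muscle markers -0.12 and metalloproteinases and inhibitors -0.23 with TIMP1. Some of these calls depended on the setting. Metalloproteinases and inhibitors stood apart to the lower side under quantile normalization, loess, a floor on the 25th percentile and the mean of all probe sets, and smooth muscle markers did so without a floor, at floors on the 25th percentile or the reporter probe sets and with a pseudocount. With the mean of all probe sets the type 1 and MHC class I lists stood apart to the lower side and the type 2 list to the higher side, and at a floor on the 75th percentile the neutrophil list stood apart to the lower side. Reference genes had a median of -0.10, which became 0.00 under quantile normalization. Random lists of unrelated genes would give 1.95 standing apart, against 1 higher and 9 lower here, with the same limit for related genes as above. The pooled SD between probe sets of the same gene was 0.22 on the log2 scale, close to the SD of the ratios themselves, and of genes with several probe sets 51.4% had all of them on the same side, against 75.3% for operated lung and sham. Random signs of a pair of probe sets would agree about as often as the 51.4% between the lungs.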

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

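Of the tests below, the one of dilution was chosen only after its result had been seen, and the second list of lymphoid genes was written after the comparisons but before its values were looked at.

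Cell cycle, B-cell and T-cell genes had lower signals in both lungs than in sham. Scaling of the arrays as the cause was tested on the cell cycle list only. Under quantile normalization, centring and loess its highest median over both comparisons was -2.014, which met the prediction set against scaling. These settings changed little, as the median ratio over all genes in operated lung and sham went from -0.113 to between -0.100 and -0.089. Meeting the prediction therefore says little. A shift common to all genes would move every list alike. Endothelial markers lay at 1.23 and 1.51, which argues against such a shift. More RNA of lymphoid cells in the sham sample is a candidate explanation that these arrays cannot decide, since those named below can also give lower lymphoid genes. A second list of lymphoid genes had a median of -1.091 or lower in both lungs, which met the prediction set for it. Of its 42 genes 16 are on the array and 12 lay above the floor, 10 of these also lay above it in both lungs, 0 belong to another list, and the most abundant, LAPTM5, CD53 and CXCR4, had log2 signals of 13.39, 13.36 and 13.18 in sham and 12.92, 12.33 and 12.61 in the non-operated lung, so lung tissue expresses most of them too. A difference between animals, a lower share of dividing lymphocytes after the procedure and a sham sample that held lymphoid tissue stay open, since 1 array per group confounds animal with procedure.

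Endothelial, alveolar type 1 and smooth muscle genes had higher signals in both lungs than in sham. If another tissue had diluted every lung cell type in the sham sample alike, alveolar type 2 genes would be higher by the same amount. Averaged over both lungs, the type 2 median of 0.67 over 9 genes lay 0.6059 below the median of the other 3 lists, more than the SD of the type 2 genes of 0.5352. Without SFTPC, whose signal lies near the top of each array, the gap was 0.580 against an SD of 0.551. In each lung the type 2 median lay below those of the other 3 lists, at 0.673 in the operated and 0.118 in the non-operated lung. The margin is small, the rule was set after the result, and the SD describes single genes and not a list median. The test therefore cannot decide on uniform dilution. Outside the test, macrophage markers had a median of 1.175 averaged over both lungs, near the 3 higher lists. Fibroblast and matrix genes lay lower, at 0.40 in the operated and 0.30 in the non-operated lung. Uniform or partial dilution may contribute, and an effect of ischemia-reperfusion in both lungs, anaesthesia or surgery, and differences between the animals were not tested.

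The operated and the non-operated lung differed little, and array noise alone was examined as an explanation for the small differences. Across 820 genes with a pair of probe sets, the log2 ratios of the pair had a Spearman correlation of 0.22, with a 95% bootstrap range of 0.150 to 0.284, against 0.69 in operated lung and sham. This range lay wholly above the bound set beforehand for pure noise. That argues against noise independent between probe sets as the only source in these genes. It also reached below the bound set for arguing against array noise, so the planned rule gave no decision. Both probe sets of a gene read the same RNA preparation. Noise that they share and an effect of the occlusion therefore cannot be told apart for these genes.

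Some lists lay on opposite sides of sham in the operated and the non-operated lung, and these differences were not tested. In that order, the medians were 0.030 and -0.026 for MHC class I genes, -0.097 and 0.059 for NADPH oxidase and nitric oxide synthase genes, 0.011 and -0.0042 for inflammasome genes, and -0.21 and 0.63 for prostaglandin and leukotriene pathway genes. The last pair is that of TBXAS1, the middle gene of its list, which lay below the floor in the operated lung, and the list median in the non-operated lung was -0.089 without the member farthest from it. The operated median was 0.38 at a floor on the 75th percentile, on the same side as the non-operated lung, and the MHC class I and inflammasome medians also changed sign under some settings. Named genes with log2 ratios to sham on opposite sides, also not tested, were RSL24D1 at 0.34 and -0.58, SCARA5 at -0.42 and 0.80, TIMP1 at -1.15 and 0.20, and YIF1A at -0.32 and 0.55. In a further group the lower lung lay at or below the floor, so its ratio is an upper limit: FAM234A at 0.27 and -0.55 or lower, FKBP10 at -0.91 or lower and 0.22, NCOA7 at 0.57 and -0.66 or lower, SLC25A11 at 0.38 and -0.27 or lower, and TBXAS1 itself at -0.21 or lower and 0.63. These genes were named for their difference between the lungs, so a value on each side of sham is partly a matter of selection. Outside the named genes, 537 of 13668 probe sets without a gene name were at least 2-fold above sham in both lungs and 422 were as far below it.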

How the results depend on the processing

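The floor at the 95th percentile of reporter probe sets was chosen after seeing the data, and the other settings were planned. No paired analysis was possible because each group has 1 array, which gives at most 1 pair and no spread to test against. Quantile normalization, centring and loess left every count within 1.5 times its main value, and 280 of 280 named values beyond 2-fold kept their direction under them. Over all settings 46 counts stayed within 1.5 times and 26 did not. Without a floor, where noise near background enters all 6765 genes, 744 genes were higher and 877 lower in operated lung and sham, 814 and 848 in non-operated lung and sham, 231 and 319 between the lungs, and 579 and 581 in both lungs against sham. Lower floors counted more dim genes between the lungs, 47 higher and 63 lower at the 25th percentile and 29 and 68 at the reporter floor. At the 75th percentile, where fewer genes are counted, there were 230 higher and 197 lower, 245 and 194, 1 and 4, and 196 and 169 in the same order, and 16 of the 31 lists with enough genes stood apart in operated lung and sham. A pseudocount, which shrinks ratios of dim genes, gave 293 lower genes in operated lung and sham, 289 in non-operated lung and sham, 0 higher and 4 lower between the lungs, and 237 lower in both. The mean of all probe sets gave 6 higher genes between the lungs.

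A list median was said to stay when it shifted by no more than the SD of its random list medians. Of the list medians 1018 stayed, 125 moved and 3 of lists standing apart changed sign. Medians within the random range also changed sign under some settings, such as those of the neutrophil and granule genes and the prostaglandin and leukotriene pathway genes in operated lung and sham, at -0.097 and 0.38 with the floor at the 75th percentile, and of alveolar type 1 cell markers between the lungs, at -0.22 with the mean of all probe sets. The angiogenic growth factors and receptors between the lungs came to -0.0078 with the mean of all probe sets. Without the farthest member, renin-angiotensin, endothelin and natriuretic peptide genes between the lungs came to 0.12 and prostaglandin and leukotriene pathway genes in non-operated lung and sham to -0.089. For named values the limit was the pooled SD between probe sets of the same gene in that comparison. Of the named values 2318 stayed, 343 moved and 1 beyond 2-fold changed sign, MS4A2 in non-operated lung and sham, at -0.017 with the floor at the 75th percentile. The cause was not tested for these changes of sign. Genes near the floor limit all counts, since their signal is close to background.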

Other observations

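The test of sex below was chosen only after its result had been seen, and the lists described first were written after the comparisons but before the values of their genes were looked at.

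Lysosomal genes had slightly higher signals than sham in both lungs. Their median log2 ratio was 0.35 in the operated lung, with 17 of 25 genes above 0 and 0 beyond 2-fold, and 0.33 in the non-operated lung, both in the highest 2.5% of random lists. The protease gene CTSD was at 0.995 and 1.19 in the operated and non-operated lung, NPC1, which exports cholesterol from lysosomes, at 0.88 and 0.80, and LAMP1 at 0.72 and 0.95, whereas GM2A was at -0.91 and -0.74. These and the other genes in this part were chosen after their values were seen. Xenobiotic metabolism enzymes had a median of 0.29 in the operated lung, in the highest 2.5% of random lists, and 0.06 in the non-operated lung, within the range. The epoxide hydrolase EPHX1 was at 1.01 and 1.26 and CYP3A29, below the floor in both lungs, at -1.39 or lower, while CYP1A1, an enzyme induced through the aryl hydrocarbon receptor, was below the floor in sham, with ratios of at least 0.31 in the operated lung and at least 1.54 in the non-operated lung.

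Autophagy genes had medians of 0.12 and 0.05, within the random range, with MAP1LC3A at 1.39 and 0.58 and RB1CC1 at 1.04 and 1.10. Mitochondrial fatty acid oxidation genes had medians of 0.10 and 0.03, sterol synthesis and uptake genes -0.51 and -0.34, and proteasome subunits -0.28 and -0.25, with 24 of 29 proteasome genes below 0 in the operated lung, and these 3 lists lay within the random range too. Between the lungs the medians of these 6 lists lay between -0.10 and 0.06.

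EIF1AY, a gene of the Y chromosome, had a log2 signal of 0.69 in sham, 10.68 in the non-operated lung and 10.89 in the operated lung. Animals of different sex are a possible explanation, in which case other Y genes, where lung expresses them, should be above the floor in both lungs and below it in sham. Leaving out CD99 and its neighbour, which lie in the part of the Y chromosome shared with X, 3 Y genes were on the array and 1, EIF1AY itself, had this pattern, while SRY stayed below the floor on each array at 1.796, 4.30 and 4.98. Y genes below the floor on every array count neither for nor against a difference of sex. With 1 informative gene, animals of different sex and a fault of this probe set cannot be told apart. A difference of sex would confound each comparison with sham.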
